A study of Musca domestica with 24 samples.

How the data were processed

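Poly(A) RNA was prepared with a stranded mRNA library kit from the head and the abdomen of single adult flies, per the labels' protocols, with 1.5 µg of RNA per library and 1.2 µg for 1 GFP female head (replicate 1). The 24 libraries fall into 4 groups of 3 flies in each tissue, defined by genotypic sex and by the double-stranded RNA that was injected, and the labels call the flies biological replicates. The submitters' processing notes name CASAVA 1.8, HISAT2, HTSeq 0.9.1 and DESeq2 1.16.1 without saying which step each tool served. The genome build and the annotation release are not given in the sources used here.

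The authors deposited 1 table per tissue with 16540 genes each, of which 12681 carry a Muller element. Its expression columns are normalized counts per the file headers, a signal made by dividing each gene's read count by 1 size factor per library. Dividing by the worth of 1 read in each library gave whole reads for 100% of values above 0, within a tolerance of 0.001, so depth could be recovered. The deposited tables also hold the authors' log2 fold changes and adjusted p-values for 4 comparisons and a mean signal per gene, per the file headers. These were used only for the sentences that name the authors' deposited table and to find which libraries each comparison used. The tissues were scaled separately, so normalized counts were not compared between tissues. Deviations from the group means within each tissue were correlated across them. Only the test for abdominal material in 1 head library compared levels between tissues, as reads scaled to the library total.

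Genes are named as in the tables: 16443 have identifiers that start with LOC, 44 are tRNA genes and 53 have other symbols. The reference gene table matched 13644 of the identifiers and pairs them with symbols alone, so lists defined by gene descriptions could be matched by symbol only. Of 18 lists fixed beforehand, only immune effectors had members, 4 genes. The lists for sex determination, yolk proteins, eggshell, ovary germline, sperm and testis, seminal fluid, pheromone and hydrocarbon synthesis, chemosensory, vision, small RNA machinery, digestive enzymes, heat shock, ribosomal proteins, muscle, fat body, neural, and juvenile hormone and ecdysone had 0 matched genes and gave no result. This reflects the matching, since genes such as Sxl, yp3 and HSP70 were measured under symbols that the lists did not match. Groups of symbols (such as cytochrome P450 genes and partners, serpins or chaperonin subunits) were therefore formed after the gene names were read, and the level of 1 symbol, AQP, had been seen by then. The knockdown target Md-tra itself is not analysed here, so the RNAi was not checked at its target.

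Values were taken as log2(normalized count + 1), and genes were kept when at least 3 of the 12 libraries of a tissue reached 10. This left 12537 genes in the abdomen, 10415 with a Muller element, and 12237 in the head, 10152 with one. Group means were compared with limma 3.58.1 (R 4.3.3), with a trended prior, in a fit over all 12 libraries of a tissue that share 1 estimate of the spread, without a block. The plan had edgeR for raw counts and limma for normalized values, and the unit found decided for limma. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of genes with few counts. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives; edgeR called 10322 genes for the sex difference in the abdomen and 2961 in the head, and every other edgeR count stands beside its limma count. Floors of 3 reads and intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

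Comparisons were GFP females against GFP males, N against GFP females, SR against GFP males, N against SR, N against GFP males and the interaction of genotype and treatment by the titles. SR against GFP females and the interaction by the column headers were added after the headers had been read, since headers and titles assign N and SR differently. Gene sets were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Positions were tested with Fisher's exact test for each Muller element, two-sided, in 1 family of 96 tests. Genes known by identifier were named by a rule, per comparison and direction those with the largest log2 change among called genes with a mean of at least 50 in the higher group and no overlap between groups, of which the first 2 or fewer are given. Genes with a symbol fall outside that rule, and which of them to name was chosen after their values were seen. The comparisons, the filter, the tests, the rule and most alternatives were fixed before the data were examined. Paralogs and overlapping genes share reads in ways that the tables do not resolve, and identifiers carry that uncertainty.

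Replicates of 1 group differed by more than sampling noise in every pair (chi-square over degrees of freedom of at least 63.9), so each library counted as 1 fly. Same-numbered libraries were compared by the correlation of their deviations from the group means. For SR and GFP male abdomens all 3 pairs were above 0.1 (0.18 to 0.46), and the fit with the replicate number as a block called 14 genes in place of 20, and that with the library code number, which pairs the same libraries there, called 1; the labels do not say what the number stands for. In the other comparisons at least 1 pair was at or below 0.1.

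The fits were tested on simulated data, with counts drawn from the gene means, library sizes and dispersions of these libraries. Known changes were given to 100 genes sampled from element A and 100 from the other elements. For N against SR, those element A genes were also changed the opposite way in GFP females. No other difference between groups was set. For a 4-fold change limma recovered 33 of 100 genes for the abdominal sex difference (12340 genes run), 37 of 100 for N against SR abdomens (12346 genes), 54 of 100 for the sex difference in heads (12124 genes) and 47 of 99 for N against SR heads (12111 genes). For a 2-fold change it recovered 1 of 99, 0 of 100, 4 of 100 and 3 of 100. False calls by limma were 12.8%, 9.76%, 6.45% and 9.09% of the calls. For DESeq2 they were 30.4% to 40.1%, so DESeq2 was less strict than limma in these simulations. Each simulation changed only 99 or 100 genes per fold change, and the shares recovered and falsely called depend on how many genes differ. They cannot be carried over to comparisons such as the abdominal sex difference, where limma called 9737 of 12537 genes. The alternatives tried were TMM scaling, edgeR, DESeq2, pseudocounts of 0.5 and 5, no filter, a minimum of 50, a log2 change of at least 1, fits of the compared groups alone, blocks by replicate number and by the number in the library code, array weights, leaving out each library in turn and, added later, thinning to equal depth.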

Results

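RNA from heads and abdomens of single house flies, Musca domestica, was sequenced after injection of double-stranded RNA against Md-tra or against GFP. Md-tra is the house fly transformer gene, whose product is needed for female development, and GFP is absent from the fly and serves as the control target. The strain carries the male determiner on the third chromosome, which is Muller element A, 1 of the chromosome arms that are conserved among flies. Each tissue had 4 groups of 3 flies: GFP RNAi females, GFP RNAi males and 2 groups that received Md-tra double-stranded RNA and were all phenotypic males per the labels. The libraries of these 2 groups carry the codes N and SR. Sample titles give N as genotypic females turned into males and SR as genotypic males, whereas the column headers of the deposited comparisons call the SR libraries sex-reversed males and the N libraries normal males. The groups are therefore called N and SR throughout: by the titles N minus SR is genotypic females minus genotypic males, and by the headers it is the reverse.

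Recovered reads per abdomen library were 56719614 to 77407229 in GFP females, 20916287 to 31364368 in GFP males, 24100066 to 41657177 in SR and 2689265, 16113838 and 2756581 in N replicates 1 to 3. Head libraries had 27872130 to 35498286 reads in GFP females, 57096789 to 79454339 in GFP males, 12080603 to 23355977 in N and 17156139 to 62303540 in SR. One read was worth 0.206 to 7.83 normalized counts in the abdomen and 0.373 to 2.52 in the head, so a value near 10 rested on 1 or 2 reads in the shallow N abdomens. After filtering, 12537 genes were tested in the abdomen and 12237 in the head.

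GFP female abdomens stood apart from all male abdomens. Their coordinates on the first principal component, which held 73.4% of the variance, were -335 to -258, against 80.4 to 121 for the GFP male, N and SR libraries. In heads the first component held 29.3% of the variance and separated GFP males from the other 3 groups, and the second held 18.7% and set SR replicate 2 apart at -137 from the other 11 heads at -37.3 to 50.5.

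**Figure D1:**
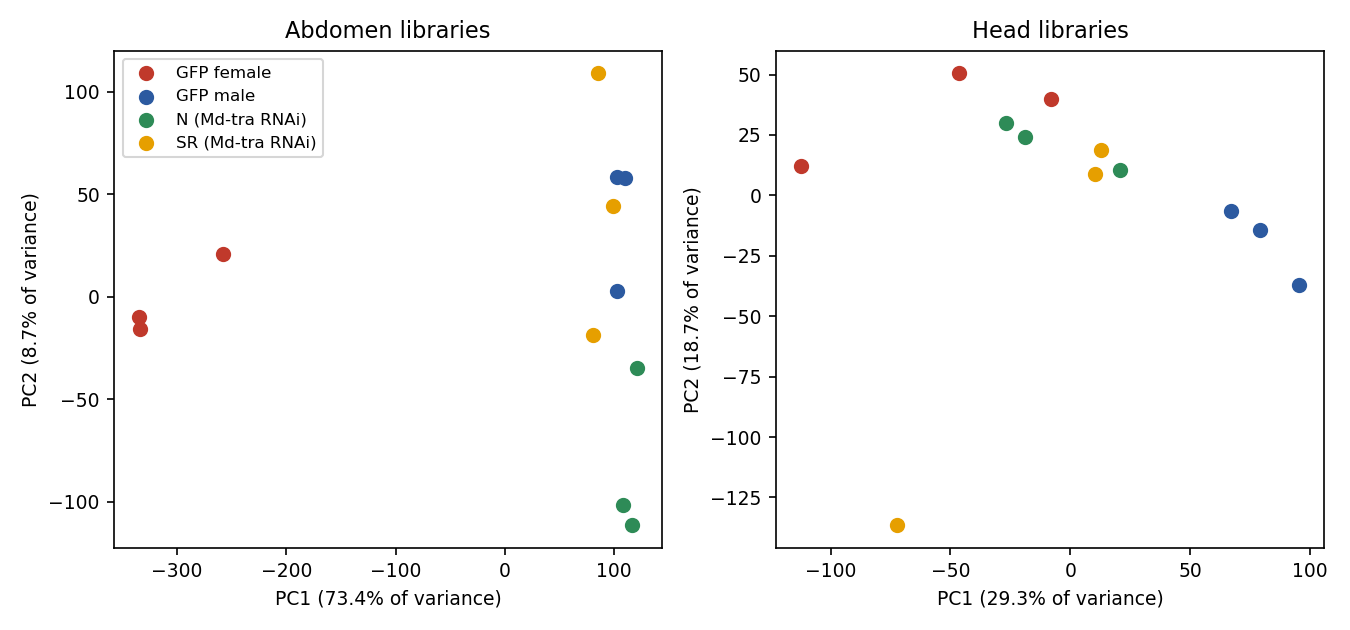
Principal components of log2(normalized count + 1) for 12 abdomen libraries (left) and 12 head libraries (right), 1 point per library, coloured by group, axes in component units with the share of variance. GFP female abdomens lie at -335 to -258 on the first component against 80.4 to 121 for all others, and SR replicate 2 lies at -137 on the second component of the heads.

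The first comparison asks how the sexes differ under control RNAi. In the abdomen, bcd, the maternal anterior determinant bicoid, had 2837 ± 557 normalized counts (mean ± SD, n = 3 per group throughout) in GFP females and no read in GFP males, at least 881-fold higher against a floor of 3 reads per library. Sxl, the house fly Sex-lethal homolog, rose 3.42-fold in females, from 662 ± 74.6 to 2271 ± 319. Armadillo, the beta-catenin of cell adhesion and Wnt signalling, was 9.06-fold higher in females at 13062 ± 786 against 1442 ± 103, and the nuclear receptor gene HR96 stood at 1188 ± 45.7 against 201 ± 53.4. All 3 measured subunits of the cytosolic chaperonin CCT were higher in females, with CCT-zeta at 10672 ± 1067 against 5047 ± 1069. The log2 differences were 11.45 ± 0.68 (SE) for bcd, 1.77 ± 0.18 for Sxl and 3.18 ± 0.19 for armadillo, with limma Benjamini-Hochberg adjusted p = 4.45e-07, 8.87e-06 and 4.23e-07.

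In GFP female abdomens, where 5549 of 12537 tested genes were lower than in GFP males, most measured genes of detoxification and defence, in groups formed after the gene names were read except for the immune effectors, were among the lower ones. As sets they did not pass camera with an estimated correlation, at a Benjamini-Hochberg adjusted p = 0.345 for the P450 group and for the immune effectors. Each library pooled the tissues of an abdomen, so tissue make-up and expression per cell cannot be told apart. Of 9 measured cytochrome P450 genes and their redox partners, 8 were lower in females and none higher. CYP6D3 had 317 ± 393 normalized counts in females against 27609 ± 5138 in males, CYP6D8 53.7 ± 77.9 against 4922 ± 2538, and CYP6A24 194 ± 217 against 21471 ± 14348. The member that passed no threshold was the P450 reductase CPR, at 7619 ± 161 and 8831 ± 1374. Both glutathione S-transferases and the esterase MdaE7 were lower in females, with GST-6A at 141 ± 111 against 7958 ± 4208. The 4 immune effectors were lower too, lysozyme at 23.1 ± 5.44 against 2096 ± 1385 and attacin at 5.23 ± 2.83 against 2490.2 ± 3902. Hsp20, a small heat shock protein, was 49.3-fold lower and the serpin SPN9 173-fold lower. By limma the Benjamini-Hochberg adjusted p was 9.76e-06 for CYP6D3, 7.67e-06 for GST-6A, 0.00271 for lysozyme, 9.05e-06 for hsp20 and 1.26e-05 for SPN9.

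As a set, the P450 group lay below other genes by camera (Benjamini-Hochberg adjusted p = 0.0322 with the preset correlation), and its adjusted p = 0.345 with an estimated correlation. The fixed list of immune effectors, 4 of 4 lower and 4 when adjusted over the list alone, gave a camera adjusted p = 0.189 with Benjamini-Hochberg adjustment. Among genes known by identifier alone, LOC101890831 on element A stood at 116356 ± 96379.8 in females against 17.7 ± 27.8 in males. LOC109612459 stood at 6.11 ± 5.32 in females against 191386 ± 11251 in males. In all, 9737 of 12537 genes differed between the sexes, 4188 higher and 5549 lower in females by limma, and edgeR called 10322. Rescaling by TMM moved the median log2 difference of all genes from -0.61 to -0.10, so that 50.1% in place of 43.0% of called genes were higher in females. Abdominal values against GFP females are shifted by 0.50 (N) and 0.48 (SR) in the opposite sense, and no called gene named in the abdominal comparisons changed sign under TMM.

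The second comparison sets each Md-tra RNAi group against GFP females, which by the titles is the effect of the knockdown in genotypic females for N and by the deposited headers for SR. Both groups differed from GFP females at most genes of the abdomen. Bcd had 3 reads in 1 N library and none in the other N or SR libraries. Sxl fell to 637 ± 96.1 in N and 776 ± 79.5 in SR, and armadillo to 1402 ± 201 and 1588 ± 400.4, where GFP males had 662 and 1442. Of the 9 P450 genes and partners, 8 were higher and CPR lower in N than in GFP females, and all 9 were higher in SR. CYP6A24 lost its call in N without GFP female replicate 3 or N replicate 2. CYP6D3 reached 16768 ± 11198 in N and 12327 ± 1581 in SR, and the 3 CCT subunits were lower in both groups. The 4 immune effectors were all higher in SR, whereas 3 were higher in N, where attacin stood at 185 ± 141 and passed no threshold. The adjusted p of Sxl by limma with Benjamini-Hochberg adjustment was 5.92e-06 in N and 2.42e-05 in SR, and that of CYP6D3 was 2.02e-05 and 3.39e-05.

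The yolk protein gene yp3 varied widely between flies of 1 group. GFP female abdomens held 15574, 21.1 and 253.6 normalized counts of yp3, GFP males 975 ± 889, N 1539.6 ± 1415 and SR 12674 ± 9855. The difference of SR from GFP females passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0439), but not under TMM, edgeR or DESeq2, nor without any 1 of SR replicates 1 to 3 or GFP female replicates 2 and 3. CPR in SR lost its call under TMM and edgeR, and attacin in SR did so without any 1 of the GFP females or SR replicate 2 or 3. Identifier genes that rose in N included LOC101888773, from 0.309 to 38644 ± 13319.6, and in SR LOC101894025, from 26.2 to 593228 ± 11633. LOC101890831 fell to 37.5 ± 58.3 in N and LOC101891006 on element A from 132682 ± 104905 to 0.402 in SR. In total 9562 genes differed between N and GFP females (5284 higher in N) and 9585 between SR and GFP females (5474 higher in SR) by limma, with 10103 and 10135 by edgeR. By camera the P450 group passed for SR at a Benjamini-Hochberg adjusted p = 0.0239, with adjusted p = 0.435 under an estimated correlation, and did not for N (adjusted p = 0.125).

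Against GFP males, the question was what Md-tra RNAi leaves different between phenotypically male abdomens. By titles SR against GFP males is the knockdown in genotypic males and N against GFP males compares sex-reversed with normal males; by headers these roles are exchanged. Few genes separated SR from GFP male abdomens. LOC101899147 on element A rose from 295 ± 9.93 to 2923 ± 666, and LOC101892939 fell from 1273 ± 141 to 1.56 ± 1.42. LOC101900843 stood at 463 ± 103 against 49.96 ± 7.71, and LOC105262251 on element A had no read in SR and 69.2 ± 29.3 normalized counts in GFP males. The called genes included no gene with a symbol. The Benjamini-Hochberg adjusted limma p was 3.05e-05 for LOC101899147 and 0.00232 for LOC101892939, and by edgeR only LOC101899147 of these 4 was called. LOC101900843 lost its call without any 1 of the 6 libraries. In all 20 genes were called by limma, 8 higher and 12 lower in SR, while 815 had an unadjusted p under 0.05, edgeR called 2 and DESeq2 268. Same-numbered SR and GFP male abdomens deviated together, and the fit with the replicate number as a block called 14 genes and that with the library code number, which pairs the same libraries here, 1. Fits of these 2 groups alone called 13 and array weights 68. Without GFP male replicate 1, 2 or 3 the count was 10, 9 or 10, and without SR replicate 1 or 2 it was 9 or 13.

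N abdomens differed from GFP males at more genes. The P450 reductase gene CPR was lower in N, 3399 ± 1369 against 8831 ± 1374, and so was the serpin SPN15 at 558 ± 129 against 1194 ± 304 (limma, Benjamini-Hochberg adjusted p = 0.0178 and 0.0271). LOC109612145 and LOC109612146 had no read in GFP males and reached 16968 ± 26034 and 2986 ± 3540.5 in N. LOC109613171 fell from 3779 ± 1078 to 44.8 ± 62.1 and LOC101895737 from 86457 ± 89351 to 1047 ± 851. The count was 1113 genes, 641 higher and 472 lower in N, against 432 by edgeR and 2250 by DESeq2, 38 from the N and GFP male libraries alone and 3 with the library code number as a block. Without GFP male replicate 1, 2 or 3 it was 14, 209 or 321, without N replicate 1 or 3 it was 443 or 155, and both CPR and SPN15 lost their call without GFP male replicate 1 or N replicate 3, as SPN15 did without GFP male replicate 3. By edgeR LOC101895737 alone of the 4 identifiers was called; it lost its limma call without GFP male replicate 1 or N replicate 1, and the other 3 lost theirs without any 1 of the 6 libraries.

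The direct comparison of N with SR asks whether genotype matters once both groups have Md-tra RNAi. N abdomens had less CPR, 3399 ± 1369 against 14197 ± 2026 in SR, less prohibitin, a mitochondrial inner membrane chaperone, at 1243 ± 474 against 2936 ± 343, and less SPN15 at 558 ± 129 against 1157 ± 24.95. They had more CYB1 at 2518 ± 883 against 555 ± 318, more THY at 7374 ± 466 against 2719 ± 286, and more of the ionotropic receptor IR25a at 262 ± 117 against 75.3 ± 25.3. LOC101892939 was detected in every N library, at 7074 ± 8764, and stood at 1.56 ± 1.42 in SR. LOC101900266 on element A had 142 ± 87.9 in N and no read in SR, whereas LOC101889813 and LOC101896660 were lower in N at 15.8 ± 7.53 against 1113 ± 598 and 339 ± 419 against 11719 ± 3499.7. Adjusted p-values by limma with Benjamini-Hochberg adjustment were 0.00331 for CPR, 0.00542 for THY, 0.023 for CYB1, 0.0438 for IR25a and 0.000625 for LOC101892939. IR25a lost its call under TMM and edgeR and without any 1 of 5 libraries (N replicates 1 and 3, SR replicates 1 to 3). CYB1 lost it without N replicate 1 or 2 or SR replicate 2, and prohibitin and SPN15 without SR replicate 2. EdgeR called neither LOC101889813 nor LOC101896660, and both calls ended without N replicate 2 or 3 or SR replicate 1 or 2, and that of LOC101889813 without N replicate 1.

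By limma 1832 genes differed, 1073 higher and 759 lower in N, against 1072 by edgeR and 2885 by DESeq2. Only 101 were called from the N and SR libraries alone, 185 with the library code number as a block and 1035 with array weights, and the count without N replicate 1 or 3 was 1133 or 1039 and without SR replicate 1 or 2 it was 1031 or 518. The interaction, the change from GFP females to N minus the change from GFP males to SR, held 8419 genes in the abdomen (4663 higher) by limma and 9002 by edgeR, and 7886 (4488 higher) and 8380 with N and SR exchanged as the headers have it. Among these genes by either assignment was Sxl, with 2271 ± 319 in GFP females and 662, 637 and 776 in GFP males, N and SR.

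In heads the sexes differed at fewer genes. Yp3 was higher in GFP females, 192977 in replicate 1, 2141 in replicate 2 and 28506 in replicate 3 against 702 ± 462 in GFP males. Of 9 measured cytochrome P450 genes and partners, 3 were higher in female heads and none lower, with CYP6G4 at 44009 ± 10734 against 17789 ± 1762, CPR at 12846 ± 1881 against 5233 ± 492 and CYB1 at 4539 ± 2307 against 1135 ± 410.1. THY, MdaE7 and the superoxide dismutase SOD1 were higher in females as well, SOD1 at 1692 ± 419 against 917 ± 51.7. Para-like, named for a sodium channel gene, was the 1 symbol lower in females, 3458 ± 1319.6 against 15515 ± 3883. Sxl stood at 2763 ± 289.8 and 2090.0 ± 68.6 and passed no threshold, and bcd averaged under 1 normalized count in every head group. Benjamini-Hochberg adjusted p by limma was 0.00432 for CPR, 0.0123 for CYP6G4, 0.0116 for para-like, 0.024 for CYB1 and 0.0351 for yp3.

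LOC101889640 on element A had 15725 ± 15701 in female heads against 4.82 ± 1.45 in male heads, and LOC101890561 13529 ± 21391 against at most 2.01 in any male head. LOC101890558 had 0.895 ± 0.775 against 1010.5 ± 92.6, and LOC101892939 0.450 ± 0.780 against 270.2 ± 67.9. By limma 3137 of 12237 genes were called, 1351 higher and 1786 lower in females, and by edgeR 2961. The count was 572, 1196 or 1687 without GFP male replicate 2, 3 or 1 and 1095 or 1919 without GFP female replicate 2 or 3, while array weights raised it to 5049 and the library code number as a block lowered it to 1322. CYP6G4 and para-like lost their call without GFP male replicate 2, CYB1 without that library, GFP male replicate 3 or GFP female replicate 2, THY without any 1 of these or GFP female replicate 3, yp3 without any library but GFP female replicate 2, SOD1 without any library but GFP female replicate 1, and MdaE7 without any 1 of the 6 libraries as well as under TMM and edgeR.

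Fewer genes separated Md-tra RNAi heads from GFP female heads than from GFP male heads, 111 against 1429 for N and 20 against 550 for SR. Of the other splits of the SR and GFP female heads, the highest and the second highest both called 18 genes, close to the 20 of the real one. Against GFP females, N heads had less CPR, 5042 ± 1176 against 12846 ± 1881 (limma, Benjamini-Hochberg adjusted p = 0.0118; not called without N replicate 2 or 3), and no other symbol was called. LOC101892939 rose from 0.450 ± 0.780 to 1503 ± 1108 and LOC101889437 on element A from 4.28 ± 5.28 to 626 ± 52.1. LOC101889640 and LOC101889813, both on element A, fell to 16.6 ± 12.1 and 31.7 ± 26.1 from 15725 ± 15701 and 35307 ± 46606. SR heads against GFP females had more LOC101890558, 566 ± 531 against 0.895 ± 0.775, and more LOC101900427, 1452 ± 1412 against 38.2 ± 17.6. They had less LOC101895918, 143 ± 46.2 against 8923 ± 5191, and less LOC101896716, 1.25 ± 2.17 against 68.5 ± 40.3, and no symbol was called. EdgeR did not call LOC101900427 or LOC101896716 in SR; the first lost its limma call without GFP female replicate 2 or 3 or SR replicate 3, the second without GFP female replicate 1 or 3 or SR replicate 2 or 3. For N 111 genes were called by limma, 68 higher and 43 lower, with 63 by edgeR, 611 by DESeq2, 40 from the 2 groups alone, 53 and 30 with blocks by replicate and library code number and 223 with array weights, and leaving out N replicate 2 or 3 or GFP female replicate 2 or 3 gave 33, 44, 70 or 233. For SR 20 genes were called by limma, 11 higher and 9 lower, with 9 by edgeR, 871 by DESeq2 and 1966 at an unadjusted p under 0.05, 0 by limma from the 2 groups alone, 7 and 3 with the blocks and 253 with array weights, and leaving out SR replicate 3 or GFP female replicate 1, 2 or 3 gave 6, 76, 12 or 12. Under the preset correlation the SR comparison also passed camera for neural receptors, channels and peptide and for serpins, with Benjamini-Hochberg adjusted p = 0.00554 and 0.0169, but adjusted p = 0.233 for both under an estimated correlation, and no member was called.

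Against GFP males, SR heads had more LOC101889813, 1096 ± 1464 against 9.27 ± 1.65, and more LOC105261812, 3388 ± 386 against 163 ± 134. LOC109614219 had no read in SR heads and 154 ± 14.0 normalized counts in GFP males, and LOC101889437 fell from 568 ± 37.2 to 3.05 ± 1.39. N heads had less armadillo than GFP males, 3115 ± 343 against 6129 ± 809.8 (limma, Benjamini-Hochberg adjusted p = 0.0254), a call lost without any 1 library but N replicate 3. LOC109613699 and LOC109613437 were higher in N at 990.1 ± 1021 and 247 ± 116 against 11.9 ± 7.20 and 4.82 ± 1.02, and LOC101894693 and LOC101893423 lower at 9.13 ± 5.45 and 3.54 ± 3.12 against 10429 ± 9325 and 192 ± 48.2. SR differed at 550 genes, 185 higher and 365 lower by limma, and N at 1429, 489 higher and 940 lower, with 502 and 1263 by edgeR and 2029 and 2719 by DESeq2. Blocks by replicate and by library code number gave 202 and 72 for SR and 891 and 261 for N, array weights 2911 for SR and 4448 for N, and the N and GFP male libraries alone 2856. For SR the count without GFP male replicate 1, 2 or 3 was 236, 39 or 87 and without SR replicate 1, 2 or 3 it was 339, 342 or 195. For N it was 645, 102 or 264 without GFP male replicate 1, 2 or 3 and 279 or 143 without N replicate 1 or 2. LOC105261812 lost its call without any 1 of the 6 libraries and by edgeR, LOC101889813 without any GFP male or SR replicate 2, LOC101893423 and LOC109613699 without GFP male replicate 2 or 3 or N replicate 2, and LOC101894693 without any library but GFP male replicate 3.

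N and SR heads differed at 37 genes, 30 higher and 7 lower in N. LOC101892939 had 1503 ± 1108 in N against 4.602 ± 4.28 in SR, and LOC101889437 626 ± 52.1 against 3.05 ± 1.39. Lower in N were LOC101900203 on element A at 7.35 ± 3.69 against 118 ± 104 and LOC101896957 at 52.5 ± 31.8 against 434 ± 37.9. In GFP heads the first pair was male-biased, LOC101889437 at 568 ± 37.2 in males and 4.28 ± 5.28 in females, and the second pair female-biased, LOC101900203 at 226 ± 43.1 in females and 3.76 ± 1.54 in males. Yp3 was higher in all 3 SR libraries than in all 3 N libraries of both tissues, 16895 ± 24879 against 347 ± 270.2 in heads, but was not called in either tissue (limma, Benjamini-Hochberg adjusted p = 0.515 in heads and 0.272 in abdomens), and chance separates 3 from 3 libraries in 10% of genes. By limma with Benjamini-Hochberg adjustment, adjusted p was 0.00273 for LOC101892939 and 0.00228 for LOC101889437. LOC101900203 and LOC101896957 lost their call by edgeR and without any 1 of the 6 libraries. EdgeR called 21 genes and DESeq2 203. The limma count was 2 from the N and SR libraries alone, 21 and 1 with blocks by replicate and library code number, 101 with array weights, and 10, 16 or 18 without N replicate 2, 3 or 1 and 16 without SR replicate 1 or 3.

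**Figure D2:**
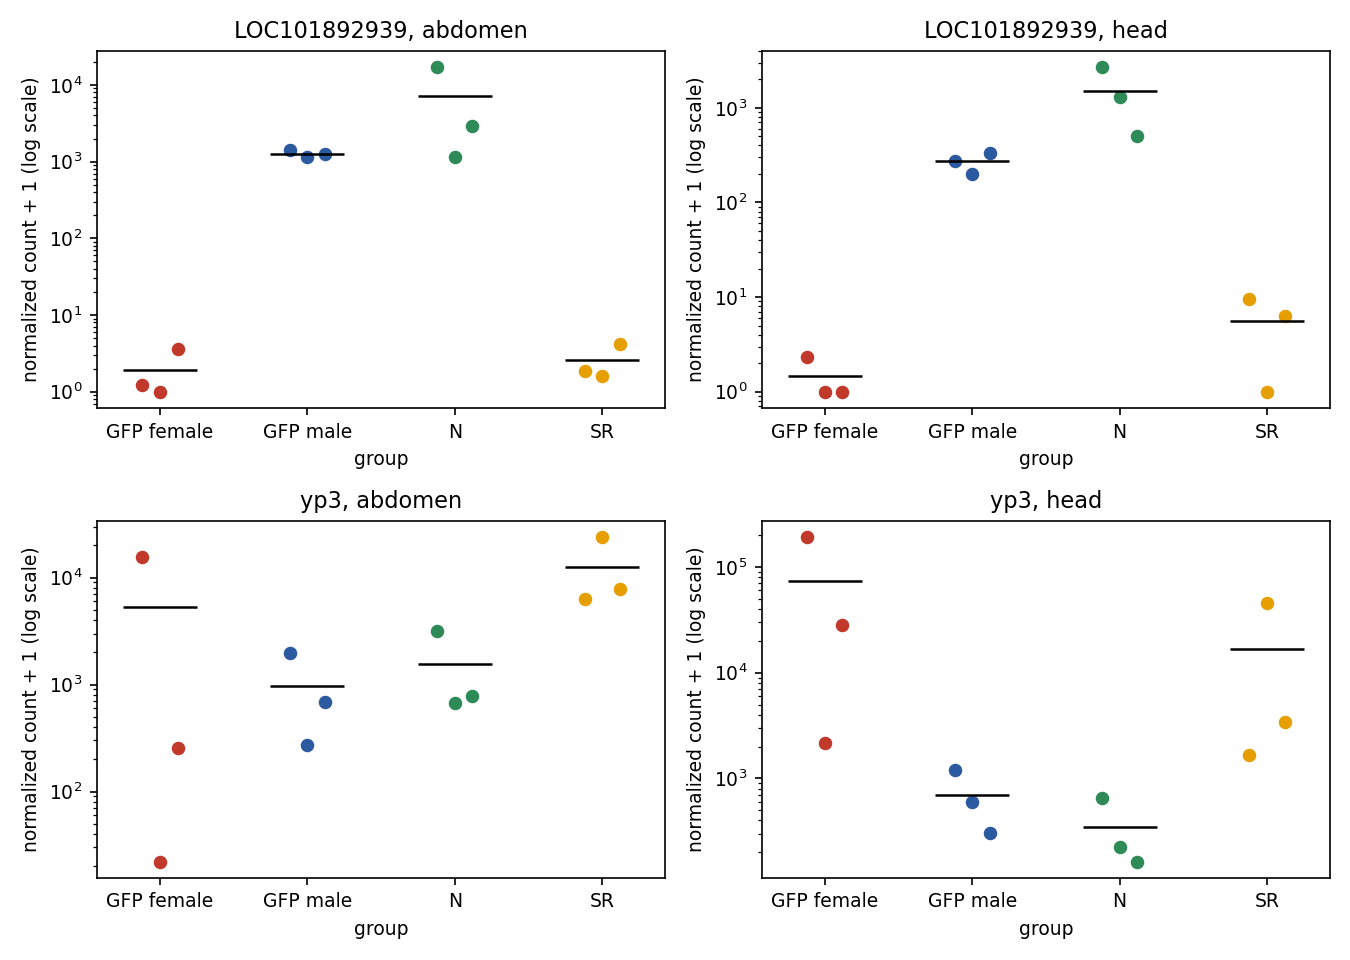
Normalized count + 1 on a log axis for LOC101892939 (top) and yp3 (bottom) in abdomens (left) and heads (right), 1 point per library and a line at each group mean. LOC101892939 averaged 270.2 in GFP male heads and 1503 in N heads against 0.450 in GFP female heads and 4.602 in SR heads.

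Because the strain's male determiner lies on element A, called genes were counted there against the other assigned genes. Elements B to F were tested alike, and where they passed the threshold they were underrepresented. Those odds ratios ran from 0.309 (element C, head interaction by titles) to 0.846 (element B, sex difference in heads). Element A held 51 of the genes called between N and GFP female heads, 2.79% of its 1829 tested genes against 0.433% elsewhere, an odds ratio of 6.60 (95% interval 4.21 to 10.4). SR against GFP male heads had 145 genes on element A (7.93% against 3.29%, odds ratio 2.53, interval 2.04 to 3.13) and N against SR heads had 16 (0.875% against 0.0721%, odds ratio 12.2, interval 4.54 to 38.2). For the sex difference in heads the odds ratio was 1.33, for SR against GFP females 4.06 from 8 genes, and for N against GFP males 1.17. SR against GFP female heads called 20 genes in all, and the highest and the second highest of the other splits of the same libraries both called 18. Fisher's exact test, two-sided and Benjamini-Hochberg adjusted over 96 tests, gave adjusted p = 1.17e-15, 3.65e-15 and 6.93e-07 for the first 3, 8.24e-06 for the sex difference, 0.0302 for SR against GFP females and 0.15 for N against GFP males. In abdomens element A was overrepresented between N and SR, with 349 genes, 18.7% against 14.1% and an odds ratio of 1.40, and the sex difference had an odds ratio of 1.11 (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.44e-05 and 0.247). SR against GFP males had 8 genes there (odds ratio 4.58) and N against GFP males 200 (odds ratio 1.29), with Fisher's exact test at Benjamini-Hochberg adjusted p = 0.0223 and 0.021, the first lost without SR replicate 1 at 4.57 and the second without any 1 of its 6 libraries at 1.03 to 1.31. The interaction by titles had 119 genes on element A in heads (odds ratio 5.72) and 1339 in abdomens (odds ratio 1.23), and that by headers had 213 and 1220 (odds ratio 1.08 in both). Fisher's exact test gave Benjamini-Hochberg adjusted p = 1.68e-32 and 0.0029 by titles and 0.593 and 0.321 by headers. By titles the head ratio was 3.098 or 9.71 without GFP female replicate 1 or GFP male replicate 2, and the abdominal one no longer passed by edgeR (1.09) or after thinning (1.11). By headers the unadjusted p passed 0.05 in heads without GFP female replicate 2 (1.41) or SR replicate 3 (1.37), and in abdomens without any 1 of the 6 GFP libraries, N replicate 2 or SR replicate 1 (1.11 to 1.14). The head odds ratio of N against SR was 4.56 and no longer past the threshold without N replicate 2, and that of SR against GFP females was lost without GFP female replicate 1 or 3 or SR replicate 1, at 1.43, 2.28 or 1.75, and by edgeR at 3.65. For N against GFP females the ratio was 3.93, 2.27 or 4.19 without GFP female replicate 1 or 3 or N replicate 1, for SR against GFP males 6.67, 4.47 or 4.23 without GFP male replicate 2 or 3 or SR replicate 3, and for N against SR 5.47 without N replicate 1 or 3 and 6.39 without SR replicate 1. Genes are not independent replicates, so these tests describe where calls fell along the genome.

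**Figure D3:**
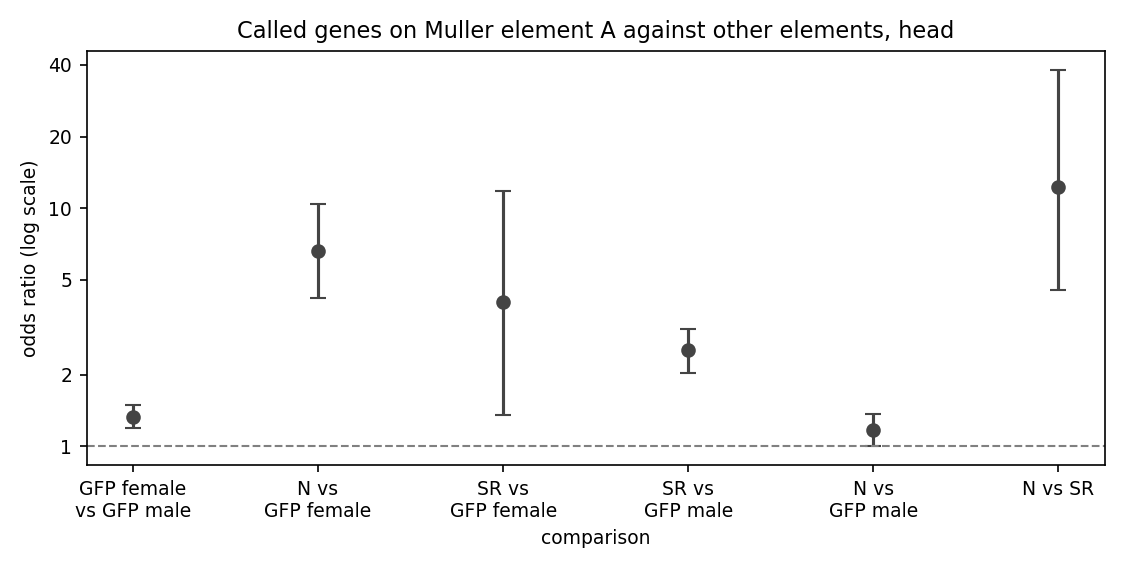
Odds ratio, on a log axis, of being called on Muller element A against the other elements in 6 head comparisons, with 95% intervals as bars and a dashed line at 1. The ratio was 12.2 for N against SR, 6.60 for N against GFP females and 1.17 for N against GFP males.

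The sex difference and the N minus SR difference share no library, so their directions were compared gene by gene. All 37 genes called between N and SR heads had a sign opposite to that of GFP females minus GFP males, 16 of them on element A, 6 on other elements and 15 without an assigned element. Of the 3137 genes that differed between GFP male and female heads, 33 were also called between N and SR, all 33 the opposite way, where independent lists would share 4.33 the same way and 5.15 the opposite way. Across genes the Pearson correlation of the 2 differences was -0.24 on element A and 0.15 off it in heads, and -0.17 and -0.11 in abdomens. By Spearman's rho the head values were -0.0323 and 0.246. Over all 12237 head genes Pearson's r was 0.036 and Spearman's rho 0.188, the sign that the titles would give. Over the 3137 sex-biased head genes the median N minus SR difference, signed by the sex difference, was 0.178 log2, thus the same way. The opposite direction in heads was therefore that of the called genes and of element A, not of most genes. In heads r on element A was -0.119 without N replicate 3 and -0.153 without SR replicate 2, and off it 0.0548, 0.0689 and 0.0916 without N replicate 1, SR replicate 1 or SR replicate 3 and 0.251 and 0.266 without N replicate 3 or SR replicate 2. In abdomens r off element A was -0.0536 without SR replicate 3. The 6 Md-tra RNAi heads can be assigned to 2 groups of 3 in 20 ways. Among these the gap of -0.391 between element A and the rest was the lowest (exact permutation p = 0.05, one-sided, the smallest 20 assignments allow). Exchanging the 2 groups reverses the sign of the gap, so a two-sided p would be larger. The plan named the correlations but neither this gap nor its direction. For r on element A by itself the exact permutation p = 0.25. In abdomens the gap of -0.0573 gave an exact permutation p = 0.2, and of 9737 sex-biased genes 1018 were called the opposite way and 466 the same way, where independent lists would share 728 and 694. By titles N would carry the female genotype and SR the male one, and by the headers N the male and SR the female one.

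**Figure D4:**
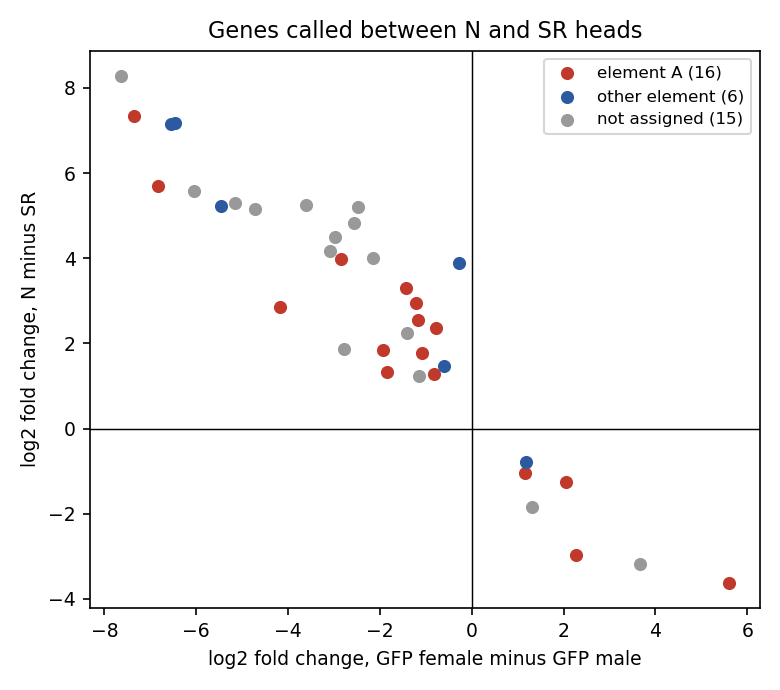
Log2 fold change of N minus SR heads (vertical) against GFP female minus GFP male heads (horizontal) for the 37 genes called between N and SR, 1 point per gene, coloured by Muller element A (16), another element (6) or none assigned (15). Every point lies in a quadrant where the 2 differences have opposite signs.

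The interaction in heads held 296 genes by the titles, 189 higher and 107 lower, and 1362 with N and SR exchanged as in the headers, 874 higher and 488 lower, with 277 and 1139 by edgeR and 1299 and 2904 by DESeq2. With the replicate number as a block limma called 143 and 197, with the library code number 136 and 0 (3855 had an unadjusted p under 0.05 by headers without a block), and with array weights 1041 and 4069. By titles CPR had an interaction of -1.96 log2 and para-like of 3.00 (limma, Benjamini-Hochberg adjusted p = 0.00652 and 0.0435). By headers armadillo had 1.31, CYB1 -2.86 and CYP6G4 -1.998, at adjusted p = 0.0348, 0.0369 and 0.0228 by limma with Benjamini-Hochberg adjustment. CPR in the 4 head groups stood at 12846 ± 1881 in GFP females, 5233 ± 492 in GFP males, 5042 ± 1176 in N and 7961 ± 1367 in SR. The first count was 728 without GFP female replicate 1, 108 or 120 without GFP male replicate 2 or 3, 168 or 136 without N replicate 2 or 3 and 181 without SR replicate 3. The second was 2624, 329 or 267 without GFP female replicate 1, 2 or 3, 578, 6 or 8 without GFP male replicate 1, 2 or 3, 123 or 14 without N replicate 1 or 2 and 493 or 545 without SR replicate 1 or 3; para-like lost its call under edgeR and without any library but GFP female replicate 1 and SR replicates 1 and 2. CYP6G4 lost it without GFP female replicate 3, GFP male replicate 2 or 3 or N replicate 1 or 2, and armadillo and CYB1 without any library but GFP female replicate 1, N replicate 3 and SR replicate 2.

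In the authors' deposited table, 11030 abdominal and 5077 head genes passed an adjusted p of 0.05 between GFP males and GFP females. Between the libraries coded SR and GFP females the authors' deposited table had 11005 genes in abdomens and 735 in heads, between N and SR 2867 and 204, and between N and GFP males 2243 and 3260. In heads 171 of those 204 were higher in N and 33 lower. The authors' deposited log2 fold changes were matched by the 3 N and 3 SR abdomens in the roles the headers give, and in heads by SR replicates 1 and 3 without replicate 2, with median absolute differences of 0.00101 to 0.00692 against 0.0466 to 0.107 for the next best choice of libraries.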

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

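The tests of exchanged titles, of depth, of SR head replicate 2, of phenotypic sex, of an incomplete change of the head and of abdominal carry-over were chosen only after the results they address were seen, as was the interaction by the column headers; the rule for genes read as on or off had been looked at over both tissues jointly before it was applied per tissue, and the limits of the carry-over test had been looked at as well. The change from GFP to Md-tra RNAi differed between the genotypes by an interaction test at 8419 abdominal and 296 head genes when N and SR are assigned by the titles, and at 7886 and 1362 when they are assigned by the headers. Of 100 groupings of the 12 abdomens 1, the real one, reached 8419 (the highest other had 7642), and 3 reached 7886 (up to 8272). Of 100 groupings of the heads 3 reached 296 (up to 875) and 2 reached 1362 (up to 2822). The interaction holds the sex difference by construction and the other groupings carry real group differences, so these ranks give no chance share for it. In heads the interaction was -1.96 log2 for CPR and 3.00 for para-like by the titles, and 1.31 for armadillo, -2.86 for CYB1 and -1.998 for CYP6G4 by the headers.

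All 37 genes called between N and SR heads, 16 of them on Muller element A, differed in the direction opposite to the difference of GFP females from GFP males, and r between the 2 differences was lower on element A than off it, the reverse of what the titles would give for genes linked to the male determiner. For the gap between r on element A and r off it, unequal depth and SR head replicate 2 are argued against. The gap was -0.403 after thinning (lowest of the other assignments -0.232) and -0.419 without that library (lowest of the others -0.147). Without that library only 10 assignments remain (exact permutation p = 0.1, the smallest they allow). By itself, r on element A was as low in 5 of 20 assignments, the real one included. The gap does not retest the signs of the 37 genes. Over all 12237 head genes r was 0.036 and Spearman's rho 0.188, the sign that the titles would give. A candidate explanation is that the genotype titles of N and SR are exchanged. By the headers, N against GFP females and SR against GFP males compare unlike genotypes. Their odds ratios of element A in heads were 6.60 and 2.53. N against SR (12.2) and GFP females against GFP males (1.33) compare unlike genotypes by either assignment. Those ratios cannot tell the assignments apart, and the second shows that unlike genotypes need not give a high ratio. By the titles, N against GFP females and SR against GFP males compare like genotypes. N against GFP males (1.17) compares like genotypes by the headers. So does SR against GFP females (4.06 from 8 genes), which goes the other way. Of 92 genes on in every GFP male head (at least 10 normalized counts) and off in every GFP female head (at most 3 reads), 7 were on in all N and off in all SR heads and 0 the reverse, where the other groupings of these 6 heads gave at most 1, though only 1 of the 7 lay on element A and 4 had no element. Any of the 92 that is on in N and off in SR runs opposite to the sex difference, as the 37 called genes do. The count is therefore not separate support for an exchange. In abdomens the same rule gave 3 against 2 among 596 genes, with up to 4 in other groupings. It cannot weigh either way there, because 1 read was worth 7.83 and 7.77 normalized counts in N replicates 1 and 3. Values within the 3 reads allowed for off could thus reach the 10 counts needed for on. Other abdominal values, picked after they were seen, leaned the way of the heads (LOC101892939 at 1273 in GFP males, 0.922 in GFP females, 7074 in N and 1.56 in SR, and 1018 sex-biased genes called the opposite way against 466 the same way). An effect of Md-tra RNAi that differs between genotypes remains untested.

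GFP male heads differed from GFP female and N heads at more genes than any pair among the other 3 groups. Their greater depth is argued against as the whole cause, since 2775 genes were called between the sexes after thinning. Phenotypic sex is argued against as the whole cause as well, since N heads, phenotypic males per the labels, differed from GFP females at 111 genes. An incomplete change of the head in the genotypic females is argued against as the whole cause: N or SR holds genotypic males under either assignment, yet SR differed from GFP males at 550 genes and from GFP females at 20, and N at 1429 and 111, with both in that order without any 1 of the 12 heads (102 and 68 for N, 39 and 5 for SR, without GFP male replicate 2). A preparation that set the GFP males apart and an effect of Md-tra RNAi in both genotypes may each remain, and neither was tested.

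SR head replicate 2 had 260 genes more than 4 times above every other head and at 10 RPM or more (RPM, reads scaled to the library total), against 0 to 15 in the other 11 heads. Carry-over of whole abdomen is argued against, since only 5 of 53 genes abundant in male abdomens (at least 500 RPM) and under 1% of that level in other heads lay above every other head. Those 5 stood at no less than 5.72% of the level in the abdomen with the same number, so that material from a part of the abdomen may remain. The highest share among all 53 genes was 371%. No biological explanation was tested for a single fly.

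Of 47 symbols measured in both tissues, 11 had GFP female and male libraries without overlap in both and in opposite directions, and 6 in the same direction. GFP female libraries lay above the males for 16 and below for 3 of the 47 in heads, and above for 12 and below for 32 in abdomens, where chance gives 10% per tissue; at those numbers independent tissues would give 11.7 opposite and 6.13 alike. The difference between tissues was not tested. Higher in female heads and lower in female abdomens were CYB1 (1.94 log2 in heads), CYP6G4 (1.28), diptericin (3.40), GST-6A (1.598), HSP70 (0.72), lysozyme (2.26), MdaE7 (0.73), SOD1 (0.85) and SOD2 (0.36), and lower in female heads and higher in female abdomens were CCT-delta (-0.33) and Mda2 (-0.32). In heads limma called only CYB1, CYP6G4, MdaE7 and SOD1, and in abdomens all but HSP70 and Mda2. The head direction of lysozyme rests on 2, 10 and 10 reads in GFP females and 4, 0 and 2 in GFP males (limma, Benjamini-Hochberg adjusted p = 0.521). Under TMM the abdominal difference of HSP70 was -0.0022 in place of -0.53, and no sign flipped.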

How the results depend on the processing

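Thinning to equal depth, the comparison of SR with GFP females, the interaction by the headers, and the left-out libraries, block and thinning for element A and r were chosen after the data were seen. TMM, pseudocounts of 0.5 and 5, no filter, a minimum of 50 and a log2 change of at least 1 left the number of called genes of all 16 comparisons within 1.5 times the reported count, and thinning did so except for SR against GFP males in abdomens (13 in place of 20). In abdomens the sex difference, N and SR against GFP females and both interactions stayed within that range under all alternatives run. For the other results below the cause was not tested. Fits of fewer libraries have less to estimate the spread from, but the count of N against GFP male heads rose in such a fit.

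EdgeR called 2 genes for SR against GFP males, 1072 for N against SR and 432 for N against GFP males in abdomens, and 63 for N and 9 for SR against GFP females and 21 for N against SR in heads. DESeq2 called more, 268, 2885 and 2250 in those abdominal comparisons and 611, 871 and 203 in those head comparisons, and in heads 2029 for SR and 2719 for N against GFP males and 1299 and 2904 for the interactions by titles and headers. Fits of the compared groups alone gave 13, 101 and 38 in those abdominal comparisons, 40, 0 and 2 in those head comparisons and 2856 for N against GFP male heads; the 0 came from limma, where the fit over all groups had 1966 genes at an unadjusted p under 0.05. Array weights gave 68 for SR against GFP males and 1035 for N against SR in abdomens. In heads they gave 5049 for the sex difference, 223 for N and 253 for SR against GFP females, 2911 for SR and 4448 for N against GFP males, 101 for N against SR, and 1041 and 4069 for the interactions.

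With the replicate number as a block, abdomens gave 9774 genes for the sex difference, 9585 for N and 9632 for SR against GFP females, 14 for SR and 923 for N against GFP males, 1788 for N against SR, and 8486 and 7911 for the interactions. Heads gave 2583 for the sex difference, 53 for N and 7 for SR against GFP females, 202 for SR and 891 for N against GFP males, 21 for N against SR, and 143 and 197 for the interactions. The numbers do not pair the libraries except in SR and GFP male abdomens. The number in the library code is partly confounded with the sex difference, N against SR, N against GFP males, SR against GFP females and the interaction by headers. Lower counts there cannot be read as an effect of the number. With that number as a block, abdomens gave 1 for SR and 3 for N against GFP males and 185 for N against SR. Heads gave 1322 for the sex difference, 30 for N and 3 for SR against GFP females, 72 for SR and 261 for N against GFP males, 1 for N against SR, and 136 and 0 for the interactions, the 0 by limma where edgeR without a block called 1139 and 3855 had an unadjusted p under 0.05 without a block.

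Of the sex-biased genes, edgeR called 618 in place of 1018 the opposite way and 267 in place of 466 the same way between N and SR abdomens, and 20 in place of 33 the opposite way in heads, as did the block (20). Fry passed 5 tests of fixed lists where camera passed 0. The odds ratio of element A lost its call for SR against GFP males in abdomens by edgeR (4.57), for N against GFP males in abdomens by edgeR (1.19) and with the block (1.15), and for SR against GFP females in heads by edgeR (3.65) and with the block (3.42), and for the interaction by titles in abdomens by edgeR (1.09) and after thinning (1.11), and the unadjusted p of the abdominal sex difference passed 0.05 with the block (1.14).

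Leaving out 1 library leaves 2 flies in an arm, with a spread pooled over all groups. In abdomens the lowest and highest counts were 8921 and 9456 for the sex difference, 8839 and 9587 for N and 8689 and 9259 for SR against GFP females, 9 and 21 for SR and 14 (without GFP male replicate 1) and 1366 for N against GFP males, 518 (without SR replicate 2) and 2091 for N against SR, and 7731 and 8547 and 6967 and 7898 for the interactions by titles and headers. In heads they were 572 (without GFP male replicate 2) and 3891 for the sex difference, 33 and 233 for N and 6 and 76 for SR against GFP females, 39 and 342 for SR and 102 and 1447 for N against GFP males, 10 and 37 for N against SR, and 108 and 728 and 6 and 2624 for the interactions; the libraries that moved a count are named with each comparison above. Odds ratios of element A in abdomens ran from 1.096 to 1.18 for the sex difference, 1.04 to 1.14 for N and 0.984 to 1.06 for SR against GFP females, 4.57 to 7.63 for SR and 1.03 to 1.31 for N against GFP males 1.38 to 1.78 for N against SR, and 1.157 to 1.25 and 1.06 to 1.14 for the interactions by titles and headers. In heads they ran from 1.22 to 1.85, 2.27 to 8.15, 1.43 to 10.65, 3.04 to 6.67, 1.15 to 2.05, 4.56 to 11.5, 3.098 to 9.71 and 0.91 to 1.52 in the same order. Correlations on element A ran from -0.192 to -0.116 in abdomens and -0.316 to -0.119 in heads, and off it from -0.139 to -0.0536 and from 0.0548 to 0.266.

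Of 271 results for named genes, none reversed and 98 lost their call under at least 1 alternative or left-out library. By setting the losses were 52 with the code block, 35 by edgeR, 30 after thinning, 24 in fits of the compared groups, 21 at a log2 change of at least 1, 15 under TMM, 15 with the block, 12 by DESeq2, 11 without a filter, 6 with array weights, 3 and 2 with pseudocounts of 5 and 0.5, and 2 with a minimum of 50. Alternatives for the knockdown target were not run, the interactions have no fit of fewer groups, and odds ratios of 0 or without a finite value were left out. Depth limits the abdomens most, where thinning to 2689265 reads kept 10161 genes, against 12080603 reads and 11212 genes in heads.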

Other observations

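The tests and values of the first 2 paragraphs were chosen after the values were seen, whereas the test of same-numbered heads and abdomens and the counts over other groupings were set down beforehand. In heads, MdRdl, a GABA receptor subunit gene, stood higher in every Md-tra RNAi library than in every GFP library, a pattern that did not follow sex. It had 17.2 ± 8.34 normalized counts (mean ± SD, n = 3) in GFP females and 21.8 ± 4.99 in GFP males, against 179 ± 70.8 in N and 112, 1728 and 98.0 in SR replicates 1 to 3. By limma with Benjamini-Hochberg adjustment it was not called, at adjusted p = 0.136 for N and 0.1 for SR against GFP females and 0.0641 and 0.0572 against GFP males, while edgeR called the last at a Benjamini-Hochberg adjusted p = 0.0393. LOC101894693 ran the other way in heads, with means of 4198 and 10429 in GFP females and males and 9.13 and 37.0 in N and SR, although 1 GFP male head held only 17.9.

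Several other named genes set GFP female abdomens apart from the 3 male groups. Sgf11, which encodes a subunit of the SAGA coactivator, stood at 442 ± 25.7 in GFP females against 99.0, 94.1 and 94.5 in GFP males, N and SR, and caspase-1 at 1609 ± 168 against 458, 507 and 493. Lower in GFP females were the EGF receptor antagonist gene argos at 13.7 ± 10.5 against 208, 147 and 143, and ODC at 29.9 ± 38.3 against 1009.8, 1586 and 3364. Each of these 4 was called by limma and edgeR between GFP females and each male group, with Benjamini-Hochberg adjusted limma p of at most 0.000212. In heads Sgf11 stood at 165 in GFP females and 118 in GFP males, and none of the 4 was called there between any 2 groups by limma or edgeR.

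Libraries that carry the same number in their codes may come from the same fly. Over 11178 genes, deviations from the group mean correlated between head and abdomen with a mean r = 0.23 for the same number, from 0.070 to 0.36, and -0.12 for different numbers. The second mean is tied to the first, because deviations cancel within each group. Of all ways to pair heads with abdomens within groups, only 1, the pairing by number, reached that mean (exact permutation p = 0.000772, the smallest that these pairings can give), and the next highest was at 0.22. All 12 heads were closest to the abdomen with their own number. The values are in line with single flies that gave both libraries, and a shared preparation day per number remains open.

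For each comparison of 3 with 3 libraries there are 10 splits of the 6 libraries, too few for a share under 0.05; the real split was in every case the 1 with the most genes. In abdomens the real count and the highest of the other splits were 9737 and 0 for the sex difference, 9562 and 0 for N and 9585 and 0 for SR against GFP females, 20 and 6 for SR and 1113 and 2 for N against GFP males, and 1832 and 4 for N against SR. In heads they were 3137 and 0 for the sex difference, 111 and 1 for N and 20 and 18 for SR against GFP females, 550 and 0 for SR and 1429 and 0 for N against GFP males, and 37 and 1 for N against SR.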
